A study of Sus scrofa with 6 samples.

How the data were processed

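The samples were 6 RNA libraries from cultured pig granulosa cells, 3 held at 42 °C for 6 h and 3 kept at 37 °C. Each library was taken as 1 sample, and groups were taken from the submitters' labels. Per the labels, the submitters made stranded mRNA libraries, sequenced them as paired reads and processed them with FastQC 0.11.4, Trim Galore and STAR on the Sscrofa11.1 assembly. The counting tool, the annotation release and the normalization tool are not given in the sources used here. The deposited count table holds raw read counts per Ensembl gene, as made by the authors, with 1 column per library. The deposited normalized table holds a signal that the authors made by dividing the raw counts of 13298 genes by 1 size factor per library. Multiplying by these factors gave whole reads for 100% of its values within a tolerance of 1e-06. The rule by which the authors removed the other genes is not given in the sources used here.

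Library totals lay between 18711440 and 29606378 counts. Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 14242 of 35670 identifiers. Symbols came from the reference table for 15623 identifiers, and identifiers without one took between 7.22 and 22.3% of the counts of a library. Coordinates came from RefSeq genes matched by symbol. Intervals on shares and ratios are at the 95% level, by the Wilson method for shares, and cover counting error only.

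Heat was compared with control by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM factors and robust dispersion estimates. P-values were adjusted by the Benjamini-Hochberg method over all tested genes and called below 0.05. Abundances are TMM-scaled CPM, read counts scaled to the library total, as mean ± SD, and log2 fold changes are heat minus control ± SE. The SE was derived from the test, as the absolute log2 fold change divided by the square root of F. The common coefficient of variation between replicates was 43.6%.

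Gene lists, 35 in number, were fixed before the data were examined, as were the tests and the rule for naming genes. They cover heat shock chaperones, heat shock transcription factors, the CCT chaperonin, mitochondrial chaperones, the unfolded protein response, ATF4 targets, immediate early genes, steroidogenesis, cholesterol synthesis, granulosa cell markers, S phase, G2 and mitosis, p53 targets, apoptosis, NRF2 targets, the proteasome, ubiquitin and autophagy, extracellular matrix, nuclear and mitochondrial genes of oxidative phosphorylation, glycolysis, ribosomal proteins, ribosome biogenesis, NF-kB targets, interferon-stimulated genes, TGF-beta signalling, cold-inducible proteins, and markers of theca, stromal, smooth muscle, endothelial, leukocyte, oocyte, ovarian surface and erythrocyte cells. Members were matched by exact symbol. Lists with at least 3 tested members, 34 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over lists. Calls are also given with the correlation estimated per list.

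Genes were named by this rule. Among called genes with a symbol, a mean log2 CPM of at least 1 and no overlap between the groups, the 10 with the largest increase and the 10 with the largest decrease qualified. Up to 4 called members per list were added, by absolute log2 fold change, or the 2 members with the highest mean where none was called. HSF1, HSP70.2, HSPA8, HSP90AA1, HSPH1, DNAJB1, HSPB1, CIRBP, RBM3, STAR, CYP11A1, CYP19A1, HSD3B1, FSHR, FOXL2, GAPDH and ACTB qualified whatever their values. HSPA13, BMPR1B, HSPA1L, DNAJA4, COL1A1 and ATP6 fall outside the rule and were named after their values were seen. Not every gene that the rule names is reported here. CYP19A1, HSD3B1 and FOXL2 matched no symbol and were not analysed here.

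The test was checked on simulated data with the dispersions of the real libraries. It recovered 2, 40, 86 and 98% of 50 genes at each of 2-, 4-, 8- and 16-fold. In the same simulated data of 14242 genes it also called 12 genes that had not been changed. A rate of false calls sets these 12 against the recovered genes, not against all 14242. Each simulated library was drawn independently, so the check does not cover near-identical libraries within a group. The alternatives tried were 3 other scalings, no filter and a filter of 10 CPM in 3 samples, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, limma on the authors' normalized signal with pseudocounts of 1 and 0.5, a minimum fold of 2, an adjusted p below 0.01, glmTreat against a fold of 1.5, an estimated correlation for camera, and fry. Added after seeing the data were a fit without the libraries that stand apart, a fit with the near-identical libraries summed, a fit to reads recovered from the normalized table, and DESeq2 and limma-voom without each library.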

Results

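RNA abundance was measured by stranded mRNA sequencing in primary cultures of pig (Sus scrofa) granulosa cells, the somatic cells that surround the oocyte in the ovarian follicle. The cells came from small follicles. The heat group (n = 3) was held at 42 °C for 6 h and the control group (n = 3) at 37 °C. The submitters call the samples of a group biological replicates, but the labels do not say whether they came from separate animals or cultures. The p-values therefore measure only the spread between these samples. The deposited gene counts summed to between 18711440 and 22599356 per control library and between 20411952 and 29606378 per heat library. Of 35670 gene identifiers, 14242 had enough reads to be tested, and 11308 of those carried a gene symbol.

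The libraries of a group were not equally similar. Control 2 and control 3 had a Pearson correlation of 0.990 across genes (log2 CPM, where CPM is the read count scaled to the library total), and heat 1 and heat 2 had one of 0.991. Genes are not independent replicates, so these values only describe likeness. Both pairs differed by more than counting noise, with a chi-square per degree of freedom of 19.8 and 16.4, which repeat libraries of 1 culture can do as well. Each library was kept as a separate sample because the labels number it as one, and the values do not show whether the libraries of a pair are independent. Control 1 correlated with the other controls at 0.901 and 0.905, and heat 3 with the other heat libraries at 0.916 and 0.909. The library with the highest correlation to control 1 was heat 3, at 0.920.

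**Figure D1:**
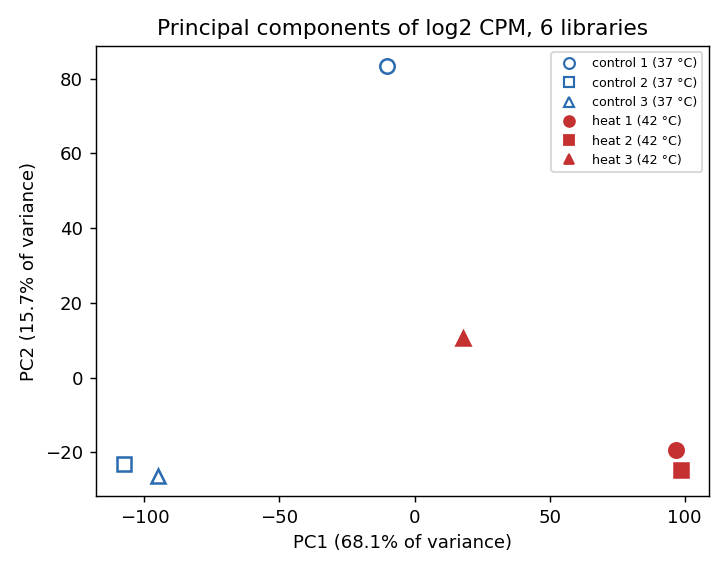
Principal components of log2 CPM over the tested genes, 1 point per library (controls at 37 °C and heat at 42 °C in separate symbols); PC1 holds 68.1% and PC2 15.7% of the variance. Control 2 and 3 lie close together, as do heat 1 and 2, with control 1 and heat 3 apart from both pairs.

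The series asks which genes of granulosa cells respond to heat. Genes of the cytosolic heat shock machinery, which folds and protects proteins, were higher in heat. HSPA6, a strictly inducible HSP70, rose from 0.496 ± 0.329 to 269 ± 201 CPM (SD, n = 3), and HSP70.2, an inducible HSP70 of the pig, rose from 129 ± 13.0 to 5497 ± 587 CPM. The co-chaperone BAG3 rose from 26.2 ± 19.7 to 502 ± 132 CPM, and the small heat shock protein HSPB8 rose from 13.0 ± 4.52 to 234 ± 30.2 CPM. Of 38 tested members of this list, 16 rose, 1 fell (HSPA13) and 21 did not pass the test, and adjusted over the list alone 20 rose and 2 fell. DNAJB1, which activates HSP70, rose from 22.4 ± 11.3 to 299 ± 182 CPM. HSPH1, an exchange factor for HSP70, rose from 126 ± 55.2 to 1515 ± 141 CPM, and the small heat shock protein HSPB1 rose from 46.8 ± 10.3 to 353 ± 52.98 CPM. The constitutive HSP70 gene HSPA8 (1415 ± 91.9 against 2877 ± 839 CPM) and HSP90AA1, the inducible HSP90 gene (2097 ± 283 against 4891 ± 427 CPM), did not pass, with edgeR adjusted p-values of 0.134 and 0.0904, although every heat library lay above every control. HSF1, the main heat shock transcription factor, stood at 4.01 ± 1.96 against 10.96 ± 0.494 CPM and did not pass either (edgeR adjusted p = 0.0649). The log2 fold change, heat minus control, was 9.03 ± 0.85 (SE) for HSPA6, 5.41 ± 0.49 for HSP70.2, 4.26 ± 0.62 for BAG3 and 4.17 ± 0.39 for HSPB8. Their edgeR adjusted p-values lay between 0.00906 and 0.0276. The list as a whole was higher than other genes (limma camera adjusted p = 1.01e-06; adjusted p = 0.686 with an estimated correlation). It took 0.737 ± 0.156% of the counts in controls and 2.28 ± 0.303% in heat (SD, n = 3). Without control 1 the test called 18 members higher and 2 lower, without heat 3 it called 19 higher and 4 lower, without heat 1 or heat 2 it called 3 higher, and without control 2 or control 3 it called 0. On Sscrofa11.1, HSPA6 lies on chromosome 4 at 88970592 to 88973109. HSP70.2 lies on chromosome 7 at 23925929 to 23927854, within the annotated span of HSPA1L (23909960 to 23938678). How reads were divided between HSP70.2 and HSPA1L is therefore uncertain, and other HSP70 copies can share reads as well.

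**Figure D2:**
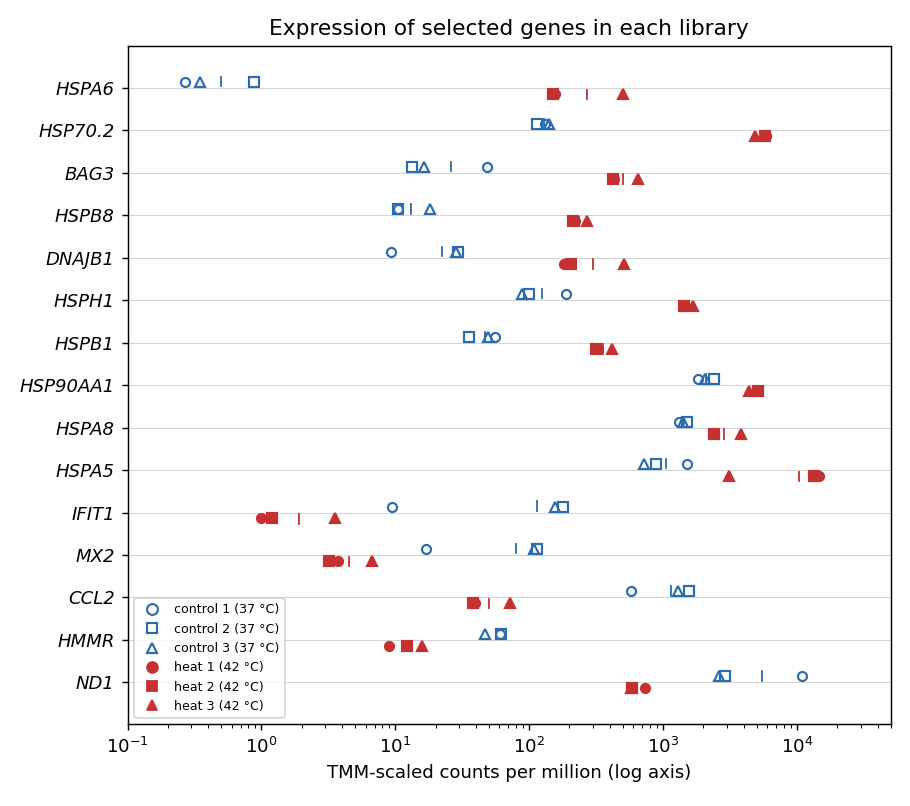
Abundance of 15 genes in each library as TMM-scaled CPM on a log axis (controls and heat in separate symbols, short lines at the group means, n = 3). HSPA6 lies below 1 CPM in every control and at 149 CPM or more in every heat library, while IFIT1, MX2 and CCL2 are lower in every heat library than in any control.

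Other genes with large increases were HS3ST3B1, a heparan sulfate sulfotransferase, RGS2, a regulator of G protein signalling, and SAMD11, TRIM16 and TENT5C. ZFAND2A, a proteasome-associated stress protein, rose from 3.64 ± 0.569 to 76.2 ± 8.76 CPM, and RGS2 rose from 0.792 ± 0.306 to 25.6 ± 6.74 CPM. HMOX1, which degrades heme, rose from 19.5 ± 17.0 to 329.6 ± 79.0 CPM, a log2 fold change of 4.08 ± 0.68 (edgeR adjusted p = 0.0276). HMOX1 belongs to the list of NRF2 targets and antioxidant enzymes, of which 28 were tested. In that list MGST1 and NFE2L2, the gene of NRF2 itself, fell. NFE2L2 went from 226 ± 48.4 to 84.3 ± 11.3 CPM. With p-values adjusted over the list alone, 2 rose and 2 fell, and the list was not called (limma camera adjusted p = 0.559). Over all genes 3 of its members were higher and 5 lower without control 1, 4 higher and 6 lower without heat 3, and 0 passed without control 2, control 3, heat 1 or heat 2.

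Genes of the endoplasmic reticulum stress response were higher in heat. HSPA5, the main chaperone of this compartment, rose from 1043 ± 423 to 10338 ± 6277 CPM, HERPUD1 rose from 102 ± 11.9 to 636 ± 237 CPM and CRELD2 rose from 6.28 ± 3.42 to 31.5 ± 16.3 CPM. Of 28 tested, 5 rose, none fell and 23 did not pass, and adjusted over the list alone 9 rose (limma camera adjusted p = 3.67e-04; adjusted p = 0.830 with an estimated correlation). DERL3 had 3 reads over the controls and 547 over the heat libraries, a ratio of 142 with a 95% interval of 48.5 to 693 that covers counting error only. HSPA5 was at 14496 and 13400 CPM in heat 1 and 2 and at 3118 CPM in heat 3. Of 26 targets of ATF4, the transcription factor of the integrated stress response, 2 rose, and 2 rose adjusted over the list alone. These were the amino acid transporter subunits SLC7A5 (7.14 ± 5.02 to 44.1 ± 16.4 CPM) and SLC3A2 (31.0 ± 1.08 to 149 ± 76.8 CPM). The ATF4 list was called (limma camera adjusted p = 0.0412; adjusted p = 0.686 with an estimated correlation). It was not called without control 1, control 2, control 3 or heat 3, with limma camera adjusted p-values of 0.150, 0.0574, 0.0828 and 0.0535. Among 25 tested immediate early genes, FOSB, IER5L and FOSL2 rose and IER3 fell, and adjusted over the list alone 4 rose and 1 fell (limma camera adjusted p = 0.00509; adjusted p = 0.686 with an estimated correlation). FOSL2 went from 38.1 ± 7.13 to 136 ± 13.1 CPM and IER3 from 41.7 ± 7.70 to 13.5 ± 4.79 CPM. The median of the immediate early genes was 3.33 log2 CPM in control 1 and 3.09 in heat 3, against 2.26 and 2.91 in control 2 and 3 and 3.92 and 3.90 in heat 1 and 2. Without control 2, control 3, heat 1 or heat 2 the test called 0 members of these lists. Without control 1 it called 13 stress response genes of the endoplasmic reticulum, 4 ATF4 targets and 11 immediate early genes higher, and without heat 3 it called 12, 6 and 5 higher. In each of these fits 1 ATF4 target and 1 immediate early gene were lower.

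Interferon-stimulated genes, the antiviral effectors induced by interferon, were lower in heat. IFIT1 fell from 114 ± 91.2 to 1.92 ± 1.41 CPM, RSAD2 from 60.4 ± 44.6 to 1.95 ± 0.252 CPM, CMPK2 from 13.9 ± 11.4 to 0.557 ± 0.142 CPM and MX2 from 80.2 ± 54.9 to 4.55 ± 1.88 CPM. Of 25 tested, 13 fell, none rose and 12 did not pass, and adjusted over the list alone 20 fell. The median log2 fold change was -2.48 (limma camera adjusted p = 3.44e-07; adjusted p = 0.736 with an estimated correlation). The fold change was -5.87 ± 1.14 for IFIT1 and -4.95 ± 0.83 for RSAD2 on the log2 scale (edgeR adjusted p = 0.0325 and 0.0276). Most of the control level came from control 2 and 3. IFIT1 was at 178 and 155 CPM there and at 9.48 CPM in control 1. The list median was 6.61 and 6.44 log2 CPM in control 2 and 3, 4.09 in control 1, and 2.61, 2.53 and 3.55 in heat 1, 2 and 3. The leukocyte marker LYZ followed the same controls, with 26.3 and 54.1 CPM in control 2 and 3 and below 1 CPM in control 1 and every heat library. PARP14, an interferon-responsive gene outside the list, fell from 55.4 ± 35.5 to 2.81 ± 0.947 CPM. Without control 1 the test called 21 members of the interferon list lower and without heat 3 it called 15, but without control 2, control 3, heat 1 or heat 2 it called 0.

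Of 19 tested inflammatory and NF-kB targets, 5 fell and 1 rose. The monocyte attractant CCL2 fell from 1150.2 ± 515 to 49.7 ± 19.1 CPM, the cytokine IL1A from 225 ± 67.7 to 26.4 ± 1.11 CPM and the chemokine CXCL8 from 50.8 ± 20.1 to 8.06 ± 2.46 CPM, while the cytokine IL11 rose from 0.171 ± 0.109 to 2.14 ± 0.2999 CPM. In this list 6 fell and 3 rose adjusted over the list alone, and the list was not called (limma camera adjusted p = 0.187). Over all genes 2 members were higher and 6 lower without control 1, 5 higher and 6 lower without heat 3, and 0 passed without control 2, control 3, heat 1 or heat 2.

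Genes of G2 and mitosis were lower in heat. HMMR, a spindle protein, fell from 56.4 ± 8.49 to 12.3 ± 3.37 CPM, the kinetochore motor CENPE from 243 ± 97.9 to 55.3 ± 11.98 CPM and the checkpoint kinase BUB1B from 39.2 ± 12.4 to 8.41 ± 4.10 CPM. Of 29 tested, 10 fell, none rose and 19 did not pass, and adjusted over the list alone 17 fell and 1 rose. The median log2 fold change was -1.05 (limma camera adjusted p = 8.10e-07; adjusted p = 0.686 with an estimated correlation). None of 30 tested genes of S phase and DNA replication passed, over all genes or adjusted over the list alone, and that list was not called (limma camera adjusted p = 0.379). Its members with the highest means, RRM1 and MCM6, stood at 96.9 ± 10.8 against 78.5 ± 6.78 CPM and 75.5 ± 13.6 against 62.8 ± 14.9 CPM. Of 21 tested p53 targets, the death receptor FAS (38.2 ± 13.1 to 8.80 ± 3.98 CPM), PMAIP1 (39.5 ± 16.1 to 9.82 ± 3.08 CPM) and TP53INP1 (110.4 ± 14.5 to 46.6 ± 6.41 CPM) fell and none rose. Another count, adjusted over the list alone, was 5 lower (limma camera adjusted p = 0.0128; adjusted p = 0.686 with an estimated correlation). SYCP2, a component of the meiotic chromosome axis, fell from 201 ± 59.3 to 12.7 ± 1.38 CPM (edgeR adjusted p = 0.00906). PTHLH, which encodes a parathyroid hormone-like factor, fell from 29.9 ± 24.8 to 1.43 ± 0.292 CPM, and SHAS2 fell from 30.4 ± 8.72 to 1.77 ± 1.55 CPM. Most of the control level of PTHLH came from control 2 and 3 (52.6 and 33.6 CPM), with 3.41 CPM in control 1. Without control 1 the test called 13 genes of G2 and mitosis lower and 3 higher, and without heat 3 it called 19 lower and 1 higher. For p53 targets these counts were 6 lower without control 1, and 8 lower and 3 higher without heat 3. For S phase they were 3 lower and 4 higher, and 7 lower and 2 higher. Without control 2, control 3, heat 1 or heat 2 the test called 0 members of these 3 lists.

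Protein-coding transcripts of the mitochondrial genome were lower in heat. ND1, a subunit of respiratory complex I, fell from 5490.5 ± 4716 to 634 ± 90.6 CPM, and CYTB, a subunit of complex III, fell from 4820.1 ± 2673 to 658 ± 205 CPM. Of 13 tested, 7 fell and 6 did not pass, and adjusted over the list alone 10 fell. The median log2 fold change was -2.43, and -1.77 without control 1 (limma camera adjusted p = 1.02e-06 with all libraries; adjusted p = 0.688 with an estimated correlation). ATP8 also fell, but its gene overlaps ATP6, so its reads are uncertain. The 13 mitochondrially encoded protein genes took 17.3 ± 6.98% of the counts in controls and 6.82 ± 1.56% in heat (SD, n = 3). Mitochondrial transcripts that encode no protein are not in this share. The highest share was that of control 1, at 25.3%, with a 95% Wilson interval of 25.29 to 25.33% that covers counting error only. Without control 1 the test called 9 of these genes lower, without heat 3 it called 4, and without control 2, control 3, heat 1 or heat 2 it called 0.

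Nuclear-encoded genes of oxidative phosphorylation (45 tested), proteasome subunits (34 tested) and ribosomal proteins (50 tested) were called lower as lists. None of their members passed, over all genes or adjusted over the list alone. The limma camera adjusted p-values were 0.00918, 0.00192 and 0.0103, and with an estimated correlation the adjusted p-values were 0.840, 0.830 and 0.840. The levels did not follow the groups. The median of the ribosomal proteins was 6.35 log2 CPM in control 1, 6.37 in heat 1 and 6.24 in heat 2, but 7.98 in control 2, 8.15 in control 3 and 8.12 in heat 3. Control 1 lay below heat 3 for oxidative phosphorylation (4.17 and 5.51) and the proteasome (5.29 and 5.94) as well. RPL4, the member with the highest mean, stood at 645 ± 183 against 405 ± 246 CPM. The members with the highest means in the other lists, ATP5F1A and PSMD2, stood at 229 ± 67.0 against 219 ± 119.9 CPM and 159 ± 19.4 against 185 ± 37.9 CPM, and the sign of each difference changed with the setting. The ribosomal protein list was not called without control 2, control 3, heat 1 or heat 2 (limma camera adjusted p = 0.0555, 0.113, 0.115 and 0.248). The oxidative phosphorylation list was not called without control 3, heat 1 or heat 2 (limma camera adjusted p = 0.0555, 0.0698 and 0.135). Without heat 3 the test called 14 genes of oxidative phosphorylation, 10 proteasome subunits and 14 ribosomal proteins lower, and without control 1 it called 9 proteasome subunits lower.

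**Figure D3:**
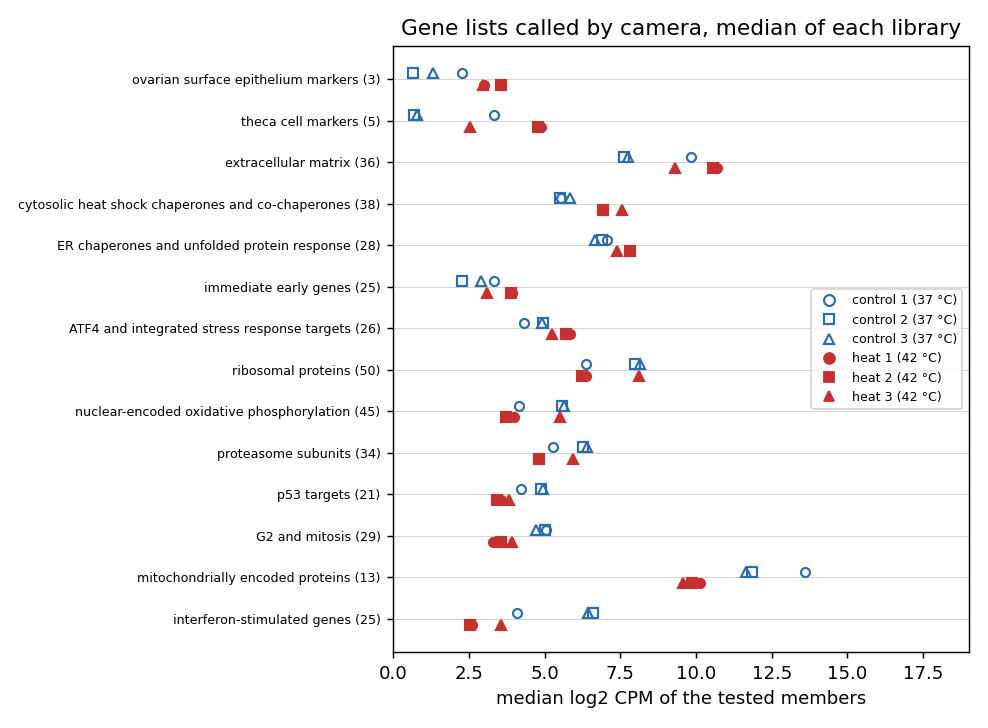
Median log2 CPM of the tested members of each of the 14 gene lists called by camera, 1 point per library (controls and heat in separate symbols). The chaperone medians of the heat libraries (6.89, 6.94 and 7.57) all exceed those of the controls (5.53, 5.50 and 5.82), whereas for ribosomal proteins heat 3 (8.12) lies beside control 2 and 3 (7.98 and 8.15).

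Extracellular matrix genes were called higher as a list (limma camera adjusted p = 0.00122; adjusted p = 0.830 with an estimated correlation). Of 36 tested, COL6A1, COL6A2 and SERPINH1 rose and POSTN fell, and adjusted over the list alone 3 rose and 1 fell. SERPINH1, the heat-inducible collagen chaperone, went from 358 ± 359.6 to 3957 ± 2219 CPM and COL6A1 from 3.35 ± 0.781 to 19.6 ± 9.57 CPM, while POSTN, a matricellular protein, went from 303 ± 249 to 10.9 ± 5.52 CPM. Most of the control level of POSTN came from control 2 and 3 (504 and 380 CPM). It was at 24.8 CPM in control 1 and at 17.3, 8.23 and 7.24 CPM in heat 1, 2 and 3. The levels of the list did not follow the groups, with medians of 9.84, 7.62 and 7.77 log2 CPM in control 1, 2 and 3 and 10.71, 10.57 and 9.32 in heat 1, 2 and 3, so control 1 lay above heat 3. The medians of the stromal markers stood in the same order for these libraries, at 6.74 in control 1 and 4.69 in heat 3. COL1A1 differed widely within the controls, with 17714 CPM in control 1 and 270 and 387 CPM in control 2 and 3. It was at 20725, 17944 and 5579 CPM in heat 1, 2 and 3 and did not pass (edgeR adjusted p = 0.560). Without control 1 the test called 25 members of the matrix list higher and 1 lower, without heat 3 it called 6 higher, and without control 2, control 3, heat 1 or heat 2 it called 0.

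Markers of other cell types also differed between libraries. Of 5 tested theca cell markers 1 rose and 4 did not pass, and adjusted over the list alone 4 rose. The theca list was called (limma camera adjusted p = 0.0435; adjusted p = 0.686 with an estimated correlation), but not without control 1, control 2, control 3 or heat 3, with limma camera adjusted p-values of 0.0504, 0.0555, 0.0828 and 0.195. Its median was 3.34 log2 CPM in control 1, 0.70 and 0.79 in control 2 and 3, and 4.87, 4.78 and 2.54 in heat 1, 2 and 3, so heat 3 lay below control 1. Of 3 tested markers of the ovarian surface epithelium, KRT8 (2.87 ± 1.68 to 10.4 ± 2.13 CPM) and UPK3B (0.206 ± 0.0110 to 1.22 ± 0.141 CPM) rose, and 3 rose adjusted over the list alone (limma camera adjusted p = 0.0244; adjusted p = 0.686 with an estimated correlation). In lists that were not called, FAP fell among 9 fibroblast and stromal markers, ERG fell among 6 endothelial markers, LYZ fell among 3 leukocyte markers and GDF9 rose among 3 oocyte markers. Adjusted over the list alone, 1 stromal and 1 endothelial marker rose, 1 stromal, 1 endothelial and 1 leukocyte marker fell, and 1 oocyte marker rose. The limma camera adjusted p-values of these 4 lists were 0.228, 0.723, 0.379 and 0.553. The stromal list was called higher without control 1 (limma camera adjusted p = 0.0236). The leukocyte list was called lower without control 1, heat 1 or heat 2 (limma camera adjusted p = 3.65e-05, 0.00253 and 0.00504), where 9 of its markers passed the expression filter in place of 3. The added markers passed through control 2 and 3, where CD163 was at 2.92 and 5.40 CPM by library total and PTPRC at 1.55 and 3.42. In every other library CD163 was at 0.15 CPM or less and PTPRC at 0. Markers let in this way come out lower in heat by that selection, so these calls are no separate evidence of a fall. Without heat 3 also 9 passed the filter, but the list was not called (limma camera adjusted p = 0.177). No member of 11 tested smooth muscle and pericyte markers passed (limma camera adjusted p = 0.723), and ACTA2 stood at 5598 ± 50.5 against 5345 ± 3142 CPM. None of the erythrocyte markers had enough reads to be tested. The fit without control 1 called 3 theca, 3 ovarian surface, 7 stromal, 4 smooth muscle, 1 endothelial and 1 oocyte marker higher, and 7 leukocyte, 1 stromal and 1 endothelial marker lower. Without heat 3 it called 3 theca, 4 ovarian surface, 2 stromal, 2 endothelial and 2 oocyte markers higher, and 1 stromal, 1 endothelial, 1 smooth muscle and 0 leukocyte markers lower. Without control 2, control 3, heat 1 or heat 2 it called 0 markers of any of these cell types.

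Genes of granulosa cell identity and steroid production gave few calls. Of 19 tested granulosa cell markers and regulators, the ovulatory protease ADAMTS1 rose from 21.2 ± 9.74 to 93.8 ± 51.3 CPM and the EGF-family ligand BTC fell from 5.22 ± 1.15 to 1.403 ± 0.523 CPM. Adjusted over the list alone 1 fell and none rose, and the list was not called (limma camera adjusted p = 0.375). None of 16 tested genes of steroidogenesis passed, over all genes or adjusted over the list alone (limma camera adjusted p = 0.615). CYP11A1, which makes pregnenolone from cholesterol, stood at 36.4 ± 7.50 against 65.3 ± 6.63 CPM (edgeR adjusted p = 0.0906), and STAR, the cholesterol transfer protein, at 0.484 ± 0.148 against 0.679 ± 0.270 CPM. Of 25 tested genes of cholesterol synthesis and uptake 1 rose, none passed adjusted over the list alone, and the list was not called (limma camera adjusted p = 0.559). FSHR, the receptor of follicle-stimulating hormone, had 6, 49 and 15 reads in control 1, 2 and 3 and 0, 2 and 0 in heat 1, 2 and 3, too few to be tested. CYP19A1, HSD3B1 and FOXL2 were not analysed here. Of 27 tested genes of TGF-beta signalling, the regulators ID1, ID2, ID3 and ID4 rose and the receptor BMPR1B fell. ID1 went from 11.9 ± 1.36 to 50.7 ± 12.3 CPM and ID3 from 54.2 ± 22.2 to 174 ± 3.23 CPM. Adjusted over the list alone 7 rose and 2 fell, and the list was not called (limma camera adjusted p = 0.396). The cold-inducible RNA-binding protein CIRBP fell from 36.2 ± 7.95 to 13.7 ± 2.24 CPM (edgeR adjusted p = 0.0384), and its relative RBM3 stood at 223 ± 113 against 101 ± 64.2 CPM and did not pass. Of 3 tested cold-inducible genes 1 fell adjusted over the list alone (limma camera adjusted p = 0.103). The test without control 1 called 8 granulosa cell genes higher and 3 lower, 4 steroidogenesis genes higher and 2 lower, 5 cholesterol genes higher, and 11 TGF-beta genes higher and 3 lower. Without heat 3 these were 2 higher and 2 lower, 2 higher and 3 lower, 5 higher and 3 lower, and 7 higher and 4 lower. Without control 2, control 3, heat 1 or heat 2 it called 0 members of these lists.

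In the remaining lists few genes passed and no list was called. Of 23 tested apoptosis regulators BCL2L11, which promotes cell death, rose from 2.13 ± 0.340 to 8.90 ± 3.54 CPM and CFLAR, which blocks death receptors, fell from 60.6 ± 15.7 to 26.9 ± 1.88 CPM. Of the list 3 rose and 3 fell adjusted over the list alone (limma camera adjusted p = 0.577). Of 23 tested genes of ubiquitin and autophagy ULK1 and ATG16L1 rose, with none adjusted over the list alone (limma camera adjusted p = 0.553). None of 4 tested genes of heat shock transcription factors passed over all genes and 1 rose adjusted over the list alone (limma camera adjusted p = 0.860). None passed, over all genes or adjusted over the list alone, among 7 subunits of the CCT chaperonin, 14 mitochondrial chaperones and proteases, 28 genes of glycolysis and hypoxia, and 33 genes of ribosome biogenesis. The limma camera adjusted p-values of these were 0.726, 0.935, 0.970 and 0.577. For mitochondrial chaperones the median log2 fold change was 0.13 while camera ranked the list lower, and for glycolysis the median was also 0.13 with camera again lower. Without control 2, control 3, heat 1 or heat 2 the test called 0 members of these lists. Without control 1 it called between 0 and 4 higher and between 0 and 5 lower per list, and without heat 3 between 0 and 7 higher and between 0 and 10 lower. HSPD1 and HSPA9, the mitochondrial chaperones with the highest means, stood at 326 ± 54.2 against 344 ± 29.8 CPM and 303 ± 30.01 against 290.2 ± 7.73 CPM. The reference genes GAPDH (684 ± 420.0 against 605 ± 299.6 CPM) and ACTB (695 ± 94.1 against 1078 ± 688 CPM) did not pass, and the sign of each difference changed with the setting.

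Over all genes, 1571 passed at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test, 956 higher and 615 lower in heat. Scaling by library size alone gave 1583 higher and 416 lower, moving the share of higher genes from 60.9% to 79.2% and the median log2 fold change of all genes from 0.05 to 0.17. The groups did not overlap for 953 and 611 of the called genes and for 37.8% of all tested genes. Chance gives 10% if all libraries are independent. It gives more if the libraries of a near-identical pair are not, so 37.8% cannot be read as an excess over chance. Of 34 tested lists 14 were called, 7 in each direction, and 0 with an estimated correlation. Without control 2 or control 3 edgeR called 0 genes (3165 and 3303 at an unadjusted p under 0.05; 1256 and 1479 by DESeq2, 0 and 2 by limma-voom). Without heat 1 it called 7 and without heat 2 it called 6 (1208 and 1242 by DESeq2, 7 and 7 by limma-voom). Without control 1 it called 4922 and without heat 3 it called 5530 (6237 and 6516 by DESeq2, 4479 and 6250 by limma-voom). HSPA6, HSPB8, DNAJA4, RGS2, TRIM16 and ZFAND2A were called both without heat 1 and without heat 2. With control 2 and 3 summed into 1 library and heat 1 and 2 into another, an alternative chosen after seeing the data, 2 genes were called, HSPA6 and RGS2.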

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

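The fits named next were chosen after seeing the data: only control 2 and 3 with heat 1 and 2, near-identical libraries summed, and reads recovered from the authors' normalized values. Of the 1571 called genes, those that an alternative fit tested kept their sign in it (100% in each). This follows largely from their selection, since 953 of those called higher and 611 of those called lower had no overlap between groups. The fits do not test all of the 1571 genes, since 67 have no value in the normalized table and the 10 CPM filter left 7649 genes. The number called was within 1.5 times under the DESeq2 size factors (1561), upper quartile factors (1627), limma-voom (1787), recovered reads (1704) and a minimum fold of 2 (1571). Library size only called 1999 (1583 higher), moving the median log2 fold change of all genes from 0.05 to 0.17. More genes entered with no filter on low counts, which called 2457 (1607 higher), and fewer with at least 10 CPM in 3 samples, which called 928 (532 higher, 396 lower). DESeq2 called 3810 (2142 and 1668), and the cause was not tested. Limma on the authors' normalized values called 2132 with a pseudocount of 1 (950 lower), the filter on low values removing 0 values and so changing nothing, and 2056 with 0.5; the cause was not tested. By their construction stricter thresholds called fewer, 10 at an adjusted p under 0.01 (9 higher, 1 lower) and 256 with glmTreat (162 and 94). The replicate block called 3404 (2104 and 1300), and 3714 on the normalized values (2220 and 1494), and the cause was not tested. Whether the replicate numbers pair the samples was not settled. Deviations from the group mean correlated at 0.30, -0.23 and 0.22 for libraries of the same number, and control 2 correlated best with heat 3 (0.29). With 3 libraries per group, 1 of them apart from the others, such correlations cannot decide it. Leaving out 1 library each gave 0 to 5530 genes, 0 to 3021 higher and 0 to 2713 lower. The high counts came without control 1 (4922) or heat 3 (5530), which leaves a near-identical pair as the whole group. The low counts, 0 to 7, came without a library of such a pair. The count thus moved with how the pairs entered, and whether the libraries of a pair are independent was not tested. Only control 2 and 3 with heat 1 and 2 called 12142 (6285 and 5857), and summing the near-identical libraries called 2 (2 higher, 0 lower), with 1692 at an unadjusted p under 0.05 in edgeR. Of 34 lists, camera called 14, 0 with an estimated correlation and 8 by fry, which tests each list on its own, and 10 to 16 under the other alternatives that use camera. The mixed test of fry, which asks for change in either direction, called 20. The lists called by fry in 1 direction are not all among the 14: they include cholesterol synthesis and cold-inducible proteins (limma fry adjusted p = 0.0460 each). They leave out the interferon (0.107), mitochondrially encoded (0.0766), endoplasmic reticulum (0.106), p53 (0.0766), matrix (0.307), proteasome (0.411), oxidative phosphorylation (0.606) and ribosomal protein (0.688) lists. ATF4 targets (limma camera adjusted p = 0.111), oxidative phosphorylation (0.358), ribosomal proteins (0.720) and the proteasome (0.0546) lost their calls when libraries were summed. Of 2117 values of 103 named genes, 1642 stayed on their side of the threshold, 390 lost the call, 52 gained it and 33 changed sign, in 8 genes of which 0 had been called. The cause was not tested. GAPDH was at 0.013 with the replicate block, 0.027 with limma-voom, 0.015 in each of the 4 fits to the normalized values and 0.26 with libraries summed. ACTA2 was at 0.077 with library size only, 0.0062 at 10 CPM and 0.12 summed, ATP5F1A at 0.036, 0.0098 and 0.23 in the same order, and HSPA9 at 0.068 with library size only and 0.070 at 10 CPM. With only control 2 and 3 and heat 1 and 2, ACTB was at -0.094, HSPD1 at -0.12, PKM at -0.29 and PSMD2 at -0.0748. Leaving out 1 library each gave -0.68 to 0.16 for ACTA2, -0.046 to 0.88 for ACTB, -0.63 to 0.15 for ATP5F1A, -0.67 to 0.13 for GAPDH, -0.048 to 0.19 for HSPD1 and -0.12 to 0.30 for PKM. FSHR and DERL3 rest on few reads, which limits what can be said of them at this depth.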

Other observations

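Genes outside the fixed lists that were called with no overlap between groups, chosen after their values were seen, included KLHL21, an adaptor of a ubiquitin ligase, which rose from 6.60 ± 1.91 to 62.0 ± 19.3 CPM. ODC1, the first enzyme of polyamine synthesis, rose from 57.3 ± 11.09 to 249 ± 7.76 CPM, the iron exporter SLC40A1 rose from 85.0 ± 3.53 to 337 ± 93.6 CPM and JMJD6 rose from 6.32 ± 0.673 to 30.5 ± 4.20 CPM. WSB1, a ubiquitin ligase adaptor, fell from 2365 ± 163 to 203 ± 60.0 CPM. The transferrin receptor TFRC fell from 247 ± 28.6 to 76.4 ± 6.35 CPM, the p53 regulator MDM4 from 106 ± 19.3 to 24.9 ± 4.60 CPM and the mitotic kinesin KIF20B from 106 ± 29.3 to 15.7 ± 2.99 CPM. Of the 1571 called genes, 67 have no value in the authors' normalized table, among them HSPA6, IFIT1, IFIT3, CMPK2, LYZ and AMPD1. The gene ENSSSCG00000018063, which carries no symbol, took 0.910, 10.8 and 12.4% of the counts in control 1, 2 and 3 (95% Wilson intervals 0.906 to 0.914, 10.82 to 10.84 and 12.34 to 12.37%), and 1.01, 1.10 and 0.564% in heat 1, 2 and 3 (1.006 to 1.015, 1.092 to 1.101 and 0.561 to 0.567%). Its edgeR adjusted p was 0.0663, and what it encodes was not determined here.

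All tests in the paragraphs that follow were chosen after the results were seen. Ribosomal proteins, oxidative phosphorylation and the proteasome were called lower in heat, but their levels in control 1 resembled heat 1 and 2, and those in heat 3 resembled control 2 and 3. An effect of heat on these lists stays open and was not separated from these differences within the groups. A swap of the labels of control 1 and heat 3 is argued against, since the chaperone median of heat 1 and 2 exceeded that of control 1 by 1.39 on the log2 scale, and that of heat 3 exceeded control 2 and 3 by 1.90. A loss of short transcripts in control 1, heat 1 and heat 2 may contribute and stays open: 358 other genes with a span under 3000 bp differed by a median of 0.32 between heat 3 and the other heat libraries (interquartile range -0.53 to 0.98) against 1.44 for the lists, and by -0.74 (-1.49 to 0.04) between control 1 and the other controls against -1.41. Span here is genomic and includes introns, so genes with a short transcript but a longer span are left out of the 358. Transcript length was not tested, so these medians cannot decide the question. A difference in the state of the cultures was not tested.

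Interferon-stimulated genes were lower in heat, with most of the control level in control 2 and 3. Leukocyte RNA as the source of these transcripts is argued against, since control 3 exceeded control 2 by a median of 0.013 (log2, interquartile range -0.05 to 0.25, 25 genes) for the interferon list but by 0.89 (0.79 to 1.13, 12 genes) for leukocyte markers, of which LYZ had 58.4, CD163 5.40 and PTPRC 3.42 CPM by library total in control 3. An effect of leukocytes on the granulosa cells of those cultures was not tested and stays open. The choice among the 4 scalings tried does not account for the difference, since the median log2 fold change lay between -2.55 and -2.43. These scalings moved the median of all genes only between -0.0040 and 0.17. They could not have removed a difference of this size, so they do not test scaling in general. Whether heat lowered these genes, or control 2 and 3 alone held them high, cannot be told apart, since control 1 exceeded the highest heat library by 0.54 on the log2 scale, less than the range of 1.02 among the heat libraries.

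Genes called higher had a median genomic span of 16.7 kb (interquartile range 8.85 to 29.9, 705 of 750 genes with a symbol) and genes called lower one of 52.2 kb (26.4 to 100.4, 443 of 471), against 31.9 kb for genes not called. With a trend along span removed from each library, the medians stood at 27.5 and 37.7 kb. The removal narrows the gap by its construction, so it does not decide whether such a trend accounts for the gap, and no biological explanation was tested. GC content and transcript length were not tested.

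The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1571 genes and the highest of the others 0, so 1 of 10 splits gave as many. For lists, the real split called 14 and the others between 6 and 13, so again 1 of 10 gave as many. Unlike the gene counts, the list counts of other splits came close to that of the real split. The number of lists called therefore says little about the grouping by heat.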
